A study of Mus musculus with 20 samples.

How the data were processed

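Lens RNA from 20 mice was measured on Affymetrix mouse genome arrays, 1 array per sample. Per the labels, each sample held both lenses of a mouse, dissected under a microscope into TRIzol, and biotin-labelled cRNA was made from 2 ug of total RNA. The samples fall into 4 groups of 5 arrays. Controls carried the E2F2 null genotype, at embryonic day 17.5 (E17.5) or at birth (P0). Triple knockout (TKO) lenses carried a Cry-Cre transgene with E2F1 and E2F2 null alleles and floxed E2F3, at the same stages. Loss of E2F2 was therefore shared by both genotypes, and the Cre transgene was present in the knockout groups only. The labels give no litter, sex, strain background or hybridisation batch.

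The authors deposited log2 expression values, 1 per probe set and array, from 1.72 to 15.0 with no missing value. That the scale is log2 was read from the values. The background correction, probe summary and normalization behind them are not given in the sources used here. Since the values were already log2, they were used as deposited, and the array medians differed by at most 0.196. No column was left unused. At most 0.142% of values were equal between any pair of arrays, so no array was a copy of another. For arrays, the number of arrays limits the precision.

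The table holds 45101 probe sets, 64 of them control probe sets. A platform annotation named a single gene for 34945 probe sets, several genes for 932 and none for 9160. Symbols of 34741 probe sets were updated by Entrez identifier through a RefSeq table of assembly GRCm38.p6. That table was used for names and for the order of neighbouring genes only. Each of 18194 genes was represented by its probe set with the highest mean over the 20 arrays. 9009 genes had more than 1 probe set. Genes were tested when that probe set lay above the array median (the 50th percentile) in at least 5 of 20 arrays, which left 11859 genes.

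Differences were tested with limma (version 3.58.1, R 4.3.3), using lmFit with 1 mean per group over all 20 arrays (16 residual degrees of freedom) and eBayes. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. Errors beside a log2 change are standard errors of the fit, and errors beside a group mean are SDs of 5 arrays. The 5 comparisons were knockout against control at E17.5 and at P0, the difference of these effects, and P0 against E17.5 in each genotype. The P-values measure the spread between samples from separate mice, whose litters are not given.

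Before the data were examined, 33 gene lists were fixed from general knowledge of E2F targets, p53, the lens and other cells of the eye. They hold 822 entries for 781 genes, of which 693 are on the array. The 31 lists with at least 5 tested genes were tested with camera in limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list and fry were run beside it. The lists of replication-dependent histones, with 4 tested genes, and of sex-linked genes, with 2, were too small to test.

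The genes named in the text follow a rule fixed at the same time. It takes E2f1, E2f2 and E2f3, the 6 largest rises and 6 largest falls among called genes whose 5 arrays of one group all lie above the 5 of the other, and up to 3 risen and 3 fallen members of each list by smallest adjusted p, or 2 members as values where none passed. For the difference of effects and the changes between stages it takes the 5 largest in each direction. Xist and Y-linked genes were left out, because the sex of the pups is not in the labels. The rule named 205 genes.

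The fit was tested on simulated data with the measured spread of each group, in which 200 of 11859 genes were changed. Noise was drawn independently for each gene, so correlation between genes was left out. The shares of false calls hold for that setting and are not estimates for the measured calls. For P0, 97.0% of 67 genes changed by 1 log2 unit and 73.1% of 67 changed by 0.5 were recovered, and 6.74% of the calls were false. For E17.5 the shared spread was too small, since the knockout E17.5 arrays vary most, and 28.1% of the calls were false. With only the E17.5 arrays in the fit, 7.78% were. For the change between stages in knockout lenses, the false share was 37.9% with all groups and 5.52% with only the groups compared. For the difference of effects it was 12.8%, and for the change between stages in control lenses 0.565%. The design was kept as fixed. Gene counts from fits of only the groups compared are given for E17.5 and for the change between stages in each genotype. For P0 no such count is given, and lists and genes that lost their call in that fit are named.

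Alternatives fixed beforehand were quantile normalization, centring of each array on its median, no filter and a stricter filter (75th percentile), the mean of the probe sets of a gene, every probe set on its own, leaving out probe sets that can match several transcripts, a variance trend with robust estimation, array weights, fits of only the groups compared, an estimated correlation between list members, and leaving out each array in turn. Alternatives chosen after seeing the data were leaving out knockout E17.5 replicates 24 and 28 together, Xist as a covariate, and the mean of the retina marker list as a covariate. Splits of the arrays were drawn 100 at a time, the real split included, from the 126 distinct splits of 10 arrays into 2 groups of 5. For the difference of effects and the correlation between stages, 5 of the 10 arrays of each stage were drawn at random instead, and a split could recur. Differences in array quality and in list medians were tested by exact permutation of the 10 arrays of a stage, whose smallest possible p is 0.00794. Figures were drawn with matplotlib 3.10.9.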

Results

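Gene expression was measured in lenses of control mice (E2F2 null) and of triple knockout mice (Cry-Cre, E2F1 null, E2F2 null, floxed E2F3) at embryonic stage E17.5 and at birth (P0), with 5 arrays in each of the 4 groups. The E2F proteins are transcription factors that drive genes of DNA replication and cell division. Per the series' design text, the study asked which events precede the collapse of lenses that lack all 3 factors. Array medians lay between 5.05 and 5.25 (log2), and the number of arrays limits the precision. The mean correlation of a control array with its own group was 0.990 to 0.993. In the knockout groups it was 0.955 to 0.978 at E17.5 and 0.979 to 0.987 at P0. Knockout E17.5 replicates 24 and 27 correlated more with the controls of their stage (0.985 and 0.990) than with their own group (0.969 and 0.972). Replicates 25, 26 and 28 correlated more with their own group. The median SD of a gene was 0.0963 in control E17.5, 0.204 in knockout E17.5, 0.103 in control P0 and 0.150 in knockout P0 arrays.

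Several properties of the arrays moved with genotype. The Gapdh 5' minus 3' probe signal, a sign of RNA length, was higher in knockout arrays by 0.199 at E17.5 and by 0.180 at P0 (exact two-sided permutation p = 0.00794 at each stage, the smallest possible, adjusted p = 0.0317 over 8 tests). The 18S ribosomal RNA signal was higher in knockout E17.5 arrays by 0.75 (exact p = 0.0159, adjusted p = 0.0317), and its difference at P0 was -0.354 (exact p = 0.0635, adjusted p = 0.0816). The actin 5' minus 3' signal was higher in knockout P0 arrays by 0.153 (adjusted p = 0.0317), and its difference at E17.5 was 0.138 (adjusted p = 0.0816). Xist, expressed from the inactive X chromosome, was above 8 (log2) in 3 of 5 control and 4 of 5 knockout arrays at E17.5, and in 3 of 5 control and 5 of 5 knockout arrays at P0.

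Of the targeted genes, E2f1 mRNA was higher in knockout lenses. It rose from 7.21 ± 0.04 to 7.81 ± 0.17 at E17.5 and from 7.34 ± 0.14 to 7.79 ± 0.14 at P0 (mean log2 ± SD, n = 5), a change of 0.60 ± 0.08 (SE, adjusted p = 0.000409) and 0.44 ± 0.08 (adjusted p = 0.000871). A dimmer E2f1 probe set went from 6.69 to 7.31 and from 6.78 to 7.34. The dimmest one went from 4.26 to 3.98 and from 4.40 to 4.39. For E2f3 the change was -0.07 ± 0.09 (adjusted p = 0.626) at E17.5 and -0.06 ± 0.09 (adjusted p = 0.659) at P0. For E2f2, null in both genotypes, it was -0.09 ± 0.06 (adjusted p = 0.347) and -0.04 ± 0.06 (adjusted p = 0.631). Whether these probes lie inside the deleted parts is not given in the sources used here, so the mRNA levels do not check the loss of the proteins.

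**Figure D1:**
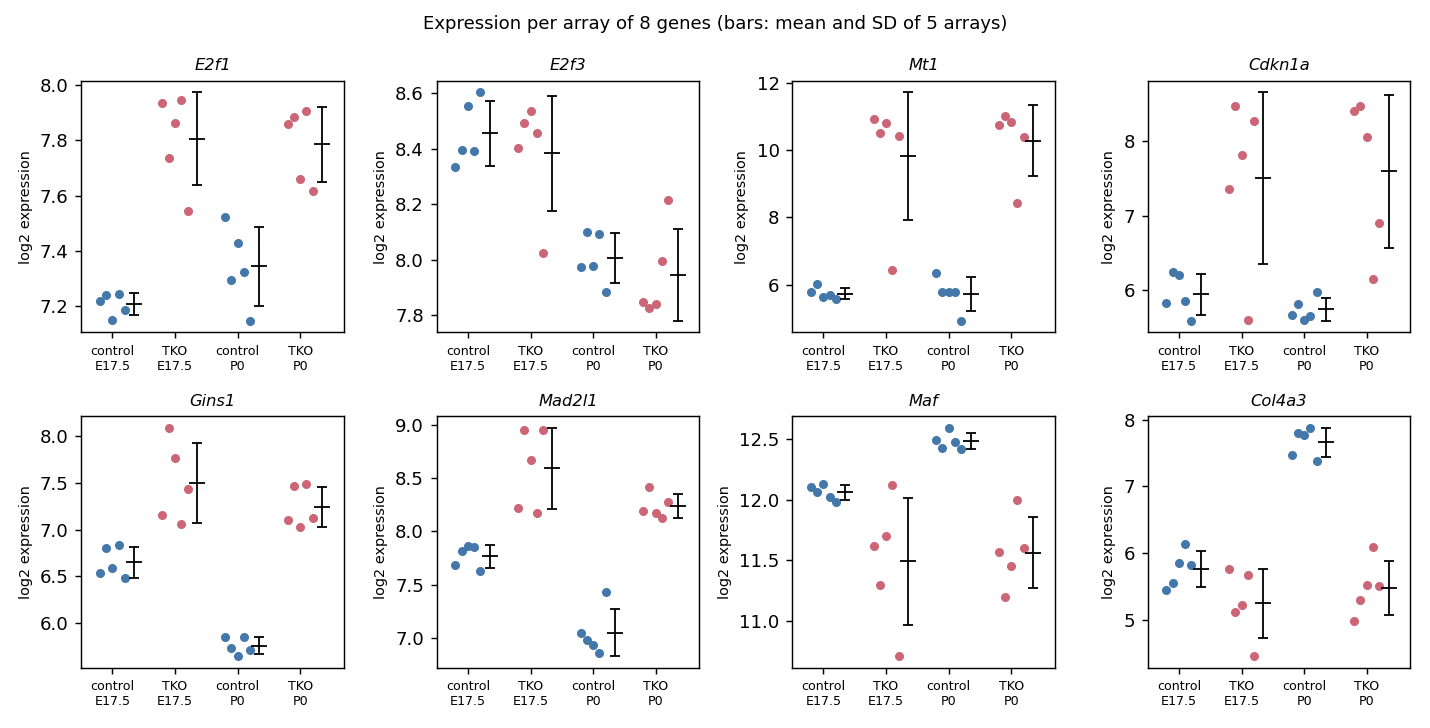
Log2 expression (vertical axes) of 8 genes in the 20 arrays, 1 point per array, grouped by genotype and stage, with the mean and SD of 5 arrays. Mt1 in knockout E17.5 replicate 27 lies at 6.45, below the other knockout arrays of that stage.

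At E17.5, 20 of 47 genes of DNA replication, 12 of 44 of mitosis, 3 of 16 of the G1 and S phases and 6 of 36 targets of the tumour suppressor p53 were higher in knockout lenses. By exact permutation of the list medians, 0 of 31 lists passed (8 at an unadjusted p below 0.05, smallest adjusted p = 0.164). By fry 7 of 31 lists passed, among them replication (adjusted p = 0.0354), G1 and S (0.0440) and p53 targets (0.0485), while mitosis and nucleotide synthesis (0.113 each) and DNA damage (0.0632) did not. The largest rise was that of Mt1, a metal-binding metallothionein, from 5.74 ± 0.18 to 9.82 ± 1.90 (SD, n = 5), a change of 4.08 ± 0.65 (SE, adjusted p = 0.00097), while its other probe set changed by 1.01. Ptgfr, the receptor for prostaglandin F2-alpha, rose by 1.34 ± 0.30 and Cenpw, a centromere protein, by 1.14 ± 0.24. Serinc3 rose by 1.10 ± 0.10, 6820431F20Rik by 1.16 ± 0.20 and Serpinb6b by 1.40 ± 0.40. The change of Serinc3 was as low as 0.21 over the 33 other settings of the processing, 1 of which ended its call. Among the falls, Olfml3 changed by -1.65 ± 0.43, Card14 by -1.13 ± 0.20 and the aldo-keto reductase Akr1b8 by -1.03 ± 0.20. The cell death gene Bmf changed by -1.01 ± 0.16, Dmrta2 fell too (adjusted p = 0.0299), and Aldh18a1, an enzyme of proline synthesis, changed by -0.85 ± 0.11. In all, 1541 of 11859 genes passed, 657 higher and 884 lower, of which 25 rose and 12 fell at least 2-fold. Without overlap between the groups were 1180 genes (9.95%), where chance gives 0.794%.

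The list of replication licensing and fork genes had 20 risen, 0 fallen and 27 not passing of 47 genes at E17.5 (30 risen when adjusted over the list alone), with a median change of 0.39. Rpa2, which binds single-stranded DNA, rose by 1.06 ± 0.13 and Gins1, part of the replicative helicase, by 0.85 ± 0.15 (SE, adjusted p = 7.69e-05 and 0.00303). Of 44 mitosis genes, 12 rose, 0 fell and 32 did not pass (13 risen when adjusted over the list alone, median 0.30), among them Mad2l1 of the spindle checkpoint by 0.82 ± 0.14 and Pttg1, securin, by 1.47 ± 0.38. Pttg1 lay at 10.29 in control replicate 12 and at most at 8.88 in the other controls of that stage. Of 16 cyclins and kinases of G1 and S, 3 rose, 0 fell and 13 did not pass (9 risen when adjusted over the list alone, median 0.30), with Cdk2 at 0.72 ± 0.15 and Cdc25a at 0.79 ± 0.17. Of 14 genes of nucleotide synthesis, 4 rose, 0 fell and 10 did not pass (4 risen when adjusted over the list alone, median 0.16), with Shmt1 at 0.87 ± 0.18 and the ribonucleotide reductase subunit Rrm1 at 0.54 ± 0.12. By camera, the adjusted p was 1.83e-16 for replication, 4.17e-08 for mitosis, 0.000147 for G1 and S, and 0.00655 for nucleotide synthesis. With an estimated correlation the adjusted p was 0.606 for replication and for G1 and S, and 0.630 for mitosis and nucleotide synthesis. Retina markers varied among the same knockout arrays. Their median deviation from the controls was 1.72, 1.33 and 0.62 in knockout replicates 25, 26 and 28, where that of the replication list was 0.84, 0.55 and 0.51. In replicates 24 and 27 it was -0.39 and -0.06, where that of replication was 0.22 and 0.02. With the mean of the retina markers as a covariate, chosen after seeing the data, the 4 lists were still called by camera, with 16 replication, 3 mitosis, 2 G1 and S and 4 nucleotide synthesis genes risen.

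Of 36 p53 target genes, 6 rose, 0 fell and 30 did not pass at E17.5 (13 risen and 2 fallen when adjusted over the list alone, median 0.20). Cdkn1a, the CDK inhibitor p21, went from 5.94 ± 0.27 to 7.51 ± 1.15 (SD, n = 5) and Phlda3 rose by 1.20 ± 0.32. Of 34 genes of DNA damage response and repair, 5 rose, 0 fell and 29 did not pass (5 risen when adjusted over the list alone, median 0.20), with the checkpoint kinase Chek1 at 0.60 ± 0.15. Camera gave an adjusted p of 0.000147 for both lists, and an adjusted p of 0.606 with an estimated correlation. Of 6 CDK inhibitors, 1 rose, Cdkn1a. Of 26 genes of the apoptosis machinery, 2 rose (Cycs, cytochrome c, and Xiap), 2 fell (Bmf and Bak1) and 22 did not pass (2 risen and 3 fallen when adjusted over the list alone, camera adjusted p = 0.907). The call of Xiap ended in 17 of 32 other settings of the processing. The Gapdh and 18S signals differed between the same arrays, the retina markers varied among them as given above, and with the retina covariate 1 p53 target and 1 DNA damage gene rose. Camera still called both lists there, p53 targets with a median of 0.196 (adjusted p = 0.000698) and DNA damage with 0.160 (adjusted p = 0.00107).

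Lens genes moved little as lists at E17.5. None of 16 crystallins, the bulk proteins of the lens, passed by limma (0 also when adjusted over the list alone), and the smallest p belonged to Crybb2 at 0.81 ± 0.34 (adjusted p = 0.116). Of 25 genes of fibre structure, 2 rose and 1 fell (2 and 3 when adjusted over the list alone). Of 24 lens epithelium genes, 2 rose and 1 fell (2 and 2 when adjusted over the list alone). Of 23 lens transcription factors, 3 rose, among them Prox1 by 0.46 ± 0.08, and 2 fell, Sox1 by -0.73 ± 0.19 and Maf by -0.57 ± 0.18 (3 and 3 when adjusted over the list alone). The change of Prox1 was as low as 0.04 over the 33 other settings of the processing, 1 of which ended its call. The call of Maf ended in 23 of these 33 settings and that of Sox1 in 2. Of 23 capsule and matrix genes, 1 rose and 4 fell, among them the perlecan gene Hspg2 by -0.50 ± 0.09 and the collagen gene Col4a4 by -1.59 ± 0.47 (1 and 5 when adjusted over the list alone). The camera adjusted p was 0.703 for crystallins, 0.907 for fibre structure, 0.963 for lens epithelium and for lens transcription factors, and 0.338 for capsule and matrix.

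In the fit of the E17.5 arrays alone, 343 genes passed, 188 higher and 155 lower, with 8 risen in replication, 7 in mitosis, 1 in p53 targets and 0 in the lists of G1 and S, nucleotide synthesis and DNA damage. Named above, Dmrta2, Cdk2, Cdc25a, Shmt1, Rrm1, Cdkn1a, Chek1, Xiap, Sox1, Maf and Col4a4 did not pass there, while the camera calls of the 6 lists held. With the retina covariate 1013 genes passed and Crybb2 was called at 1.08 ± 0.31 (SE, adjusted p = 0.0416). Not called there were Serpinb6b at 1.37 ± 0.43, Dmrta2 at -0.87 ± 0.30, Cdkn1a at 1.42 ± 0.48, Xiap at 0.27 ± 0.09, Maf at -0.55 ± 0.19 and Col4a4 at -1.17 ± 0.41. Of the 23 calls lost among named genes, 20 kept at least 80% of the change. The nucleotide synthesis list was not called without knockout replicate 25, and neither it nor the DNA damage list with the stricter filter. The count of 1541 became 835, 994, 964, 948 and 965 without control replicates 10, 11, 12, 13 and 15, 1012 without knockout replicate 26 and 2502 without knockout replicate 27. Without replicate 27, 31 replication, 8 G1 and S, 15 p53 target and 9 DNA damage genes rose. Other splits of the 10 arrays called as many as 17 lists, so chance is not excluded for the number of lists at E17.5.

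At P0, 39 of 47 replication and 39 of 44 mitosis genes were higher in knockout lenses, and so were 17 of 36 p53 targets, 15 of 18 retina markers and 6 of 12 pigment cell markers. Among the 7 retina markers above the array median in all control P0 arrays, 4 were higher. Of 23 genes of the lens capsule and matrix 13 were lower and 4 higher, and of 24 lens epithelium genes 11 were lower and 5 higher. Mt1 had the largest rise, from 5.73 ± 0.51 to 10.28 ± 1.05 (SD, n = 5), a change of 4.56 ± 0.65 (SE, adjusted p = 0.000119), while its other probe set changed by 1.17. Reln, a secreted guide of neurons, rose (adjusted p = 0.00197). The growth factor Fgf15 rose by 2.45 ± 0.62, opticin (Optc), made by the ciliary body, by 2.47 ± 0.53, Minar2 by 2.52 ± 0.47 and Lrrn1 by 2.49 ± 0.49. With the retina covariate none of these 5 genes was called, with Fgf15 at 0.24 ± 0.29 (adjusted p = 0.613), Reln at 1.29 ± 0.58, Minar2 at 1.38 ± 0.49, Lrrn1 at 1.53 ± 0.57 and Optc at 1.74 ± 0.67. Pdgfra, the growth factor receptor of the lens epithelium, went from 9.33 ± 0.27 to 6.59 ± 1.13, a change of -2.73 ± 0.43 (adjusted p = 0.000246). Col4a3 and Col4a4, chains of basement membrane collagen, changed by -2.18 ± 0.22 and -2.66 ± 0.47. Car8 changed by -2.68 ± 0.29, Ccbe1 by -1.95 ± 0.35 and albumin (Alb), at 9.04 in control replicate 1 and at most 6.67 in the other controls, by -2.45 ± 0.47. In all, 4080 of 11859 genes passed, 2032 higher and 2048 lower, of which 316 rose and 88 fell at least 2-fold. Without overlap between the groups were 3070 genes (25.9%, chance 0.794%).

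Of the 47 replication genes, 39 rose, 1 fell and 7 did not pass at P0 (43 risen and 1 fallen when adjusted over the list alone), with a median change of 0.64. Prim1, a primase subunit, went from 6.54 ± 0.23 to 8.09 ± 0.19 and Gins1 from 5.76 ± 0.09 to 7.24 ± 0.22 (SD, n = 5), while Gmnn, which restrains licensing, rose by 1.29 ± 0.15. The fallen gene was Timeless, by -0.57 ± 0.21, which did not pass in the fit of the P0 arrays alone. Of the 44 mitosis genes, 39 rose, 0 fell and 5 did not pass (42 risen when adjusted over the list alone, median 0.77), with Mad2l1 at 1.19 ± 0.14 and the mitotic kinase Cdk1 at 1.34 ± 0.19. Of 16 cyclins and kinases of G1 and S, 10 rose, 0 fell and 6 did not pass (11 risen and 1 fallen when adjusted over the list alone, median 0.50), with Cdc25a at 1.08 ± 0.17. Of 14 nucleotide synthesis genes, 8 rose, 0 fell and 6 did not pass (8 risen when adjusted over the list alone, median 0.27), with Rrm1 at 0.97 ± 0.12. Camera gave adjusted p = 2.16e-18 for replication and for mitosis, 0.00018 for G1 and S and 0.000352 for nucleotide synthesis, and with an estimated correlation an adjusted p of 0.531 for each of them.

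Of 36 p53 targets, 17 rose, 4 fell and 15 did not pass at P0 (20 risen and 4 fallen when adjusted over the list alone, median 0.30). Cdkn1a rose by 1.86 ± 0.46 (SE, adjusted p = 0.0047), Rps27l by 0.48 ± 0.08 and the nuclease gene Aen by 0.60 ± 0.11, while Ptp4a3 changed by -0.54 ± 0.12 and Rrm2b by -0.37 ± 0.09. Of 34 DNA damage genes, 14 rose, 2 fell and 18 did not pass (15 risen and 2 fallen when adjusted over the list alone, median 0.18), with Rad51ap1 of homologous repair at 0.89 ± 0.15. Of 13 heat shock genes, 8 rose, 0 fell and 5 did not pass (8 risen when adjusted over the list alone, median 0.25), with the chaperone Hspb1 at 1.49 ± 0.29. Camera gave adjusted p = 0.000287, 0.00384 and 0.0169 for these 3 lists, and with an estimated correlation an adjusted p of 0.531 for p53 targets and heat shock and of 0.536 for DNA damage. In the fit of the P0 arrays alone the heat shock list was not called. Of 26 apoptosis genes, 4 rose, among them the death receptor Fas by 0.69 ± 0.24, and 7 fell, among them Bcl2 by -0.50 ± 0.11 (5 and 8 when adjusted over the list alone, camera adjusted p = 0.708).

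Of 24 lens epithelium genes, 5 rose, 11 fell and 8 did not pass at P0 (5 risen and 13 fallen when adjusted over the list alone, median -0.31). E-cadherin (Cdh1) went from 9.54 ± 0.23 to 7.60 ± 0.57 (SD, n = 5) and Sulf1 changed by -1.44 ± 0.22, while keratin Krt18 rose by 1.61 ± 0.32 and the tight junction gene Cldn1 by 2.32 ± 0.47. Of 23 capsule and matrix genes, 4 rose, 13 fell and 6 did not pass (4 risen and 13 fallen when adjusted over the list alone, median -0.28), with Col4a2 at -0.97 ± 0.14, Hspg2 at -0.54 ± 0.09 and versican (Vcan) at 2.08 ± 0.37. Camera gave adjusted p = 0.022 for lens epithelium and 0.0136 for capsule and matrix, and with an estimated correlation an adjusted p of 0.741 and 0.531. The lens epithelium list was not called in the fit of the P0 arrays alone. Of 23 lens transcription factors, 3 rose and 9 fell (4 and 10 when adjusted over the list alone, camera adjusted p = 0.252), with Six3 at -0.39 ± 0.07, Tfap2a at -1.45 ± 0.27 and Maf at -0.92 ± 0.18. None of 16 crystallins passed by limma (0 also when adjusted over the list alone, camera adjusted p = 0.843), and of 25 fibre structure genes, 5 rose and 4 fell (5 and 4 when adjusted over the list alone, camera adjusted p = 0.965).

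Markers of other cells of the eye moved at P0 beside these groups. Of 18 retina markers, 15 rose, 0 fell and 3 did not pass (16 risen and 1 fallen when adjusted over the list alone, median 1.58), with the transcription factor Lhx2 going from 6.30 ± 0.86 to 8.63 ± 0.22 (SD, n = 5). Rlbp1 of the visual cycle rose by 1.88 ± 0.34 and Nrl by 1.37 ± 0.25. Of the 7 markers above the array median in all control P0 arrays 4 rose and 2 had a negative change (median 0.58), and of the 11 others 11 rose (median 1.75). Of 29 retina markers on the array 18 were tested, and high values in the knockout P0 arrays alone were enough to pass the filter. The rise of the 11 others may therefore be favoured by the filter, which was not tested, and it is weak evidence by itself. Of 12 markers of pigment epithelium and melanocytes, 6 rose, 0 fell and 6 did not pass (6 risen when adjusted over the list alone, median 1.06), with the pigment gene Tyr at 2.18 ± 0.43 and Dct at 2.37 ± 0.45. Of 17 macrophage markers, 4 rose, 0 fell and 13 did not pass (2 risen when adjusted over the list alone, median 0.83), with Ctss, a lysosomal protease, at 1.42 ± 0.39. Camera gave adjusted p = 9.74e-05, 0.00217 and 0.0024, and with an estimated correlation an adjusted p of 0.531, 0.531 and 0.768. Of 23 endothelium and pericyte markers, 0 rose and 2 fell, Ednrb by -0.83 ± 0.21 and Pdgfrb by -0.91 ± 0.34 (1 fallen when adjusted over the list alone, camera adjusted p = 0.252). The Gapdh and actin signals also differed between these arrays. With the retina covariate 1498 genes passed at P0, and of 134 results for genes named by the rule 68 lost their call. Of those 68, 22 kept at least 80% of the change, and the SE was larger by a median factor of 1.29. Among them Timeless was at -0.74 ± 0.28, Fas at 0.65 ± 0.32, Ednrb at -0.71 ± 0.28 and Cdkn1a at 1.496 ± 0.599. With a smaller part of the change left, Rbl1 was at 0.33 ± 0.21, Krt18 at 0.77 ± 0.31, Cldn1 at 1.41 ± 0.54, Pdgfrb at -0.55 ± 0.44 and Ctss at 0.91 ± 0.50. Ptp4a3 was at -0.41 ± 0.16, Rrm2b at -0.28 ± 0.11, Tyr at 1.65 ± 0.55, Dct at 1.59 ± 0.54 and, from the list itself, Lhx2 at 0.996 ± 0.453, Rlbp1 at 0.996 ± 0.334 and Nrl at 0.72 ± 0.24. The calls of the DNA damage, lens epithelium, capsule, macrophage and, by construction, retina lists ended there, while replication (16 risen, median 0.42), mitosis (17, 0.51), G1 and S (2, 0.35), nucleotide synthesis (4, 0.27), p53 targets (2, 0.24), heat shock (6, 0.27) and pigment cells (1, 0.71) were still called. By exact permutation of the list medians, heat shock (adjusted p = 0.0769) and macrophages (0.0820) did not pass at P0, and by fry macrophages did not (0.117). The DNA damage list was not called at P0 with the stricter filter, nor heat shock and lens epithelium with the mean of the probe sets. Other splits of the 10 arrays called as many as 14 lists, so chance is not excluded for the number of lists at P0.

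**Figure D2:**
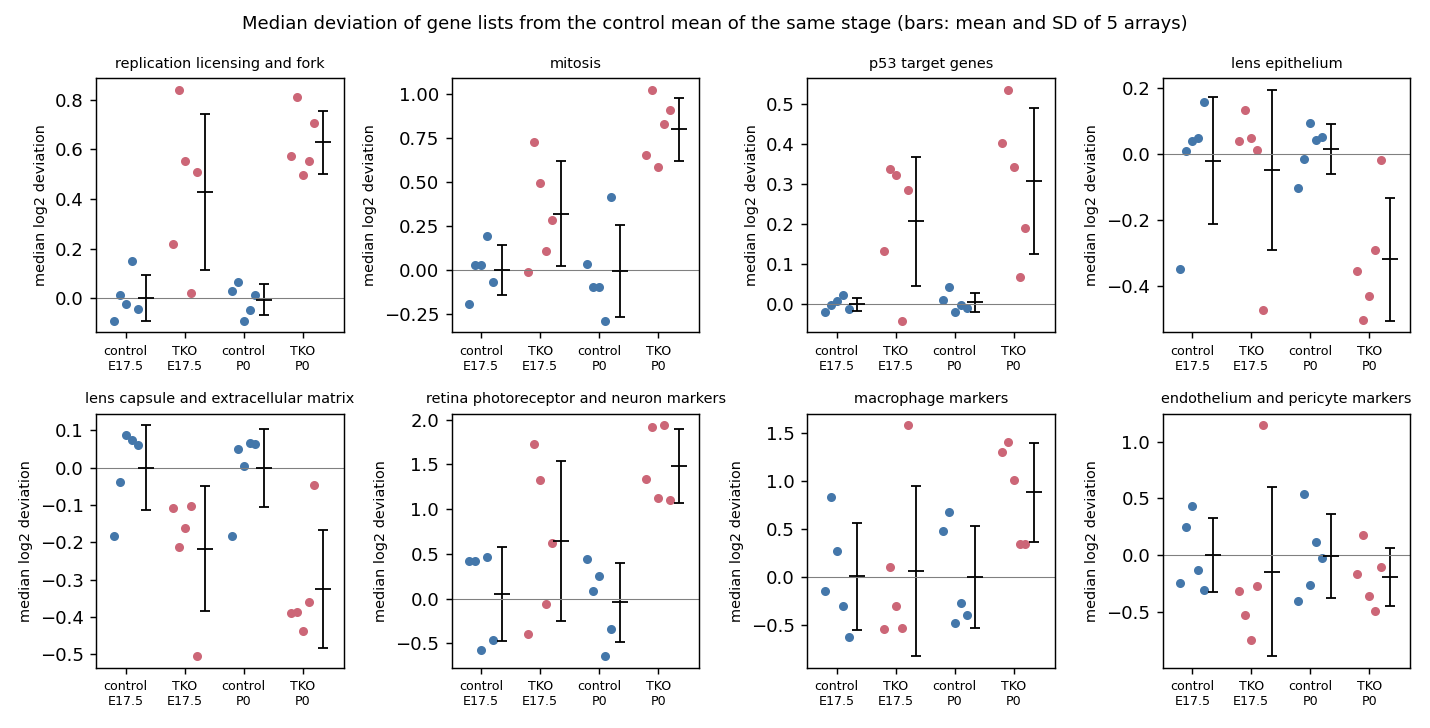
Median log2 deviation of 8 gene lists from the mean of the same-stage controls (vertical axes), 1 point per array, grouped by genotype and stage. At P0 the 5 knockout arrays lie between 0.50 and 0.81 for replication and between 0.59 and 1.02 for mitosis, above all 5 controls.

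The other lists were not called by camera in the knockout against the control. By fry, hypoxia, oxidative stress and cornea (adjusted p = 0.0440 each) and inflammation (0.0354) passed at E17.5, and hypoxia (0.00873) and oxidative stress (0.00101) at P0. By exact permutation hypoxia and oxidative stress (0.0246 each) and the unfolded protein response (0.0379) passed at P0. Some of these lists were called by camera in other settings. Without knockout replicates 24 and 28, chosen after seeing the data, endothelium (median -0.52, adjusted p = 8.0e-05), retina (0.89, 0.00131), inflammation (-0.17, 0.0223) and hypoxia (-0.15, 0.0243) were called at E17.5. Without knockout replicate 27, hypoxia (-0.19, 0.0281), retina (0.80, 0.0369) and cholesterol synthesis (-0.28, 0.0467) were. Of 28 settings, 8 called retina at E17.5, and at P0 11 called hypoxia and 7 cholesterol synthesis. At E17.5 the camera adjusted p was 0.386 for the E2F family (3 of 13 rose), 0.963 for CDK inhibitors, 0.822 for mesenchymal change, 0.640 for the unfolded protein response, 0.131 for heat shock. It was 0.0717 for hypoxia and glycolysis, 0.191 for oxidative stress, 0.970 for interferon, 0.0717 for inflammation, 0.166 for cholesterol synthesis and 0.338 for Wnt, Notch and FGF signalling. Among markers of other cells at E17.5 it was 0.0717 for retina, with 0 of 18 genes passing by limma and a median of 0.56. It was 0.622 for pigment cells, 0.786 for endothelium, 0.75 for macrophages, 0.816 for erythroid cells, 0.399 for cornea, 0.703 for mesenchyme and 0.399 for muscle. At P0 it was 0.610 for the E2F family, in which Rbl1 rose by 0.54 ± 0.17 and E2f5 changed by -0.52 ± 0.09. It was 0.708 for CDK inhibitors, 0.467 for mesenchymal change, 0.466 for the unfolded protein response, 0.0536 for hypoxia and glycolysis, 0.154 for oxidative stress, 0.445 for interferon, 0.708 for inflammation, 0.0536 for cholesterol synthesis and 0.661 for Wnt, Notch and FGF signalling. For erythroid, cornea, mesenchyme and muscle markers at P0 it was 0.418, 0.843, 0.902 and 0.708. Median, mean and test differed in sign for 7 lists at E17.5 and 5 at P0, none of them called, among them apoptosis and crystallins at both stages. Of 4 histone genes, H1f2 changed by -0.55 ± 0.21 (adjusted p = 0.0474) and H2aw by -0.50 ± 0.14 (adjusted p = 0.0112) at P0, and H3c7 and H2bc18 did not pass. The sex-linked genes Xist and Eif2s3y did not pass at either stage.

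The effects at both stages were then compared. Across the 11859 genes, which are not independent replicates, the log2 changes at E17.5 and P0 had a Pearson correlation of 0.728, with a jackknife SE over arrays of 0.137. The comparisons share no array. Called at both stages were 440 genes higher and 501 lower, where independent lists would give 113 and 153, and 7 genes were called in opposite directions, where independent lists would give 265. Of the genes called at E17.5, 92.1% had the same sign at P0.

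**Figure D3:**
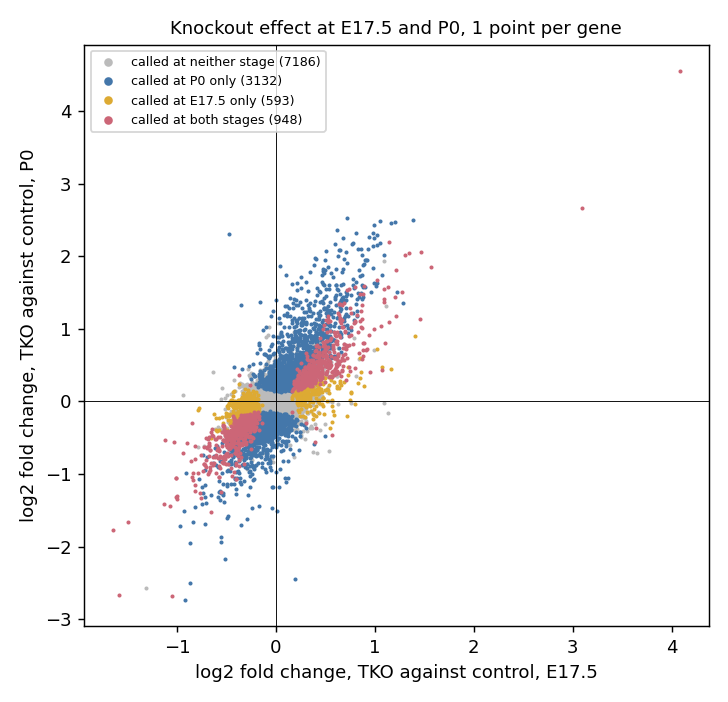
Log2 change of knockout against control at E17.5 (horizontal axis) and at P0 (vertical axis), 1 point per gene, coloured by the comparisons in which the gene passed. Of 11859 genes, 948 passed at both stages, 593 at E17.5 alone, 3132 at P0 alone and 7186 at neither.

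The test of the difference between the stages called 21 genes, 4 with a higher and 17 with a lower effect at P0 (1866 at an unadjusted p below 0.05). Col4a3, a basement membrane collagen chain, rose between the stages in controls from 5.76 ± 0.27 to 7.66 ± 0.22 and measured 5.25 ± 0.52 and 5.48 ± 0.40 in knockouts (SD, n = 5), a difference of effects of -1.66 ± 0.31 (SE, adjusted p = 0.0355). Abi3bp, a matrix protein, differed by -1.52 ± 0.27, Tafa4 by -1.17 ± 0.19, Pnisr by -1.02 ± 0.20 and the retinoic acid receptor Rarb by -0.96 ± 0.17. Ociad2 differed by 1.13 ± 0.22, Ecrg4 by 1.04 ± 0.20, Aars, which charges tRNA with alanine, by 0.77 ± 0.15 and the adenylate kinase Ak5 by 0.52 ± 0.10. The effect was more positive at P0 for replication (median 0.25, camera adjusted p = 0.000422), mitosis (0.49, 7.3e-10), retina (0.72, 0.00232), pigment cells (0.81, 0.000841) and macrophages (0.63, 0.00232), and more negative for lens epithelium (-0.26, 0.00111) and capsule and matrix (-0.15, 0.024). With an estimated correlation the adjusted p was 0.841 for each of these 7 lists, and by fry 0 of 31 lists passed (3 at an unadjusted p below 0.05, smallest adjusted p = 0.238). With the retina covariate 1 gene passed and none of the 9 genes named here did, though each kept at least 80% of the difference, with Col4a3 at -1.57 ± 0.33 (adjusted p = 0.0896). The list calls ended there for replication (median 0.09, adjusted p = 0.162), capsule and matrix (-0.18, 0.301), macrophages (0.46, 0.0523) and, by construction, retina (adjusted p = 0.672). Those of mitosis (8.37e-06), lens epithelium and pigment cells (0.0208 each) held. Median, mean and test differed in sign for the E2F family, apoptosis and the list of Wnt, Notch and FGF signalling, none of them called. The count rested on single arrays, with 0 genes left by limma without any of control P0 replicates 5, 6 and 7, control E17.5 replicates 10, 11, 12 and 15, knockout P0 replicates 17, 18 and 19 or knockout E17.5 replicate 27. It was 3 without knockout E17.5 replicate 25, 6 without control E17.5 replicate 13, and 35 without knockout P0 replicate 21. It was 48 without knockout E17.5 replicate 24, 168 without knockout E17.5 replicate 28 and 321 without knockout P0 replicate 22. Other splits of the arrays called as many as 14 lists, so chance is not excluded for the number of lists.

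Between E17.5 and P0 in control lenses, most genes of the mitosis and replication lists fell. The 18S signal moved between the same arrays too, from 9.15 ± 0.22 to 10.03 ± 0.15 (SD, n = 5), which was not tested. Of 44 mitosis genes, 39 fell and 0 rose (median -0.96), with Cep55, needed for the last step of cell division, at -1.89 ± 0.26 (SE). Of 47 replication genes, 35 fell and 1 rose (median -0.59), of 14 nucleotide synthesis genes 10 fell and 1 rose (-0.48), of 16 G1 and S genes 10 fell and 0 rose (-0.55), and of 34 DNA damage genes 14 fell and 3 rose (-0.29). Of 15 cholesterol synthesis genes, 10 fell (-0.44), of 24 genes of the unfolded protein response 13 fell and 1 rose (-0.35), and of 5 erythroid genes 3 fell (-0.33), with the haem synthesis gene Alas2 at -1.78 ± 0.48. Of 16 crystallins 3 rose and 13 did not pass (median 0.05), with Crybb2 going from 10.99 ± 0.26 to 13.52 ± 0.13 (SD, n = 5). Of 25 fibre genes 5 rose (0.16), and of 24 lens epithelium genes 4 rose (0.10). Alb rose by 2.46 ± 0.47, Clic5 by 2.01 ± 0.25, Col4a3 by 1.90 ± 0.22 and Col4a4 by 1.71 ± 0.47, while Sfrp2 changed by -2.22 ± 0.53, the retinal factor Atoh7 by -2.09 ± 0.53 and Sox11 by -1.64 ± 0.42. When adjusted over the list alone, 43 mitosis, 35 replication, 11 nucleotide synthesis, 11 G1 and S, 19 DNA damage, 13 cholesterol, 14 unfolded protein and 3 erythroid genes fell. By the same adjustment 3 crystallin, 5 fibre and 4 lens epithelium genes rose. Camera gave adjusted p = 7.69e-28 for mitosis, 6.68e-15 for replication, 2.19e-06 for nucleotide synthesis, 1.79e-06 for G1 and S and for cholesterol, and 0.000364 for DNA damage. It gave 0.00651 for the unfolded protein response, 0.0432 for erythroid genes, 0.00166 for crystallins, 0.000823 for fibre genes and 0.0273 for lens epithelium. With an estimated correlation the adjusted p was between 0.289 and 0.646 for these 11 lists, and other splits called as many as 15 lists, so chance is not excluded for the number of lists. With the retina covariate the calls of erythroid genes (median -0.33, 3 fallen, adjusted p = 0.0572) and lens epithelium (median 0.04, adjusted p = 0.0791) ended, and 2 fibre genes rose. By fry 14 lists passed, among them 10 of the 11, all but lens epithelium (adjusted p = 0.386). In all, 2046 genes passed, 583 higher and 1463 lower, and 4431 in the fit of the control arrays alone.

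In knockout lenses over the same interval, 30 of 44 mitosis genes and 19 of 47 replication genes fell, and 8 of 12 pigment cell markers rose. The median change was -0.51 for mitosis, -0.30 for replication, of which 2 genes rose, and -0.41 for the 16 G1 and S genes, of which 9 fell. Of 14 nucleotide synthesis genes 8 fell and 1 rose (-0.38), of 34 DNA damage genes 16 fell and 3 rose (-0.30), of 15 cholesterol genes 11 fell (-0.52), and of 24 genes of the unfolded protein response 13 fell and 5 rose (-0.35). Of 16 crystallins 5 rose and 11 did not pass (median 0.07), with Crybb2 at 2.07 ± 0.34 (SE), and of 25 fibre genes 9 rose, 1 fell and 15 did not pass (0.20). Of 14 inflammation genes 7 rose and 2 fell (0.29), of 12 pigment cell markers 8 rose (0.86), of 6 cornea markers 3 rose (0.36) and of 5 muscle markers 3 rose (0.36). The photoreceptor factor Nrl rose by 2.20 ± 0.25, phosducin (Pdc) by 1.70 ± 0.32, the cold-induced gene Cirbp by 1.66 ± 0.15 and Fabp7 by 1.61 ± 0.48. Dancr changed by -1.39 ± 0.15, Airn by -1.33 ± 0.21, Taf15 by -1.31 ± 0.18, Skp2, which marks p27 for breakdown, by -1.23 ± 0.17 and Slc25a37 by -1.21 ± 0.19. When adjusted over the list alone, 35 mitosis, 22 replication, 10 G1 and S, 9 nucleotide synthesis, 17 DNA damage, 12 cholesterol and 14 unfolded protein genes fell. By the same adjustment 5 crystallin, 10 fibre, 7 inflammation, 11 pigment cell, 3 cornea and 3 muscle genes rose. Camera gave adjusted p = 3.1e-07 for mitosis, 0.000281 for replication, 0.00262 for G1 and S, 0.0129 for nucleotide synthesis, and 0.00408 for DNA damage. It gave 1.6e-05 for cholesterol, 0.0343 for the unfolded protein response, 0.00455 for crystallins and for fibre genes, 0.0193 for inflammation and for muscle, 0.000141 for pigment cells and 0.0124 for cornea. With an estimated correlation the adjusted p was between 0.272 and 0.655 for these 13 lists, and other splits called as many as 17 lists, so chance is not excluded for the number of lists. Under the retina covariate 29 replication genes fell and the E2F family list was called too (adjusted p = 0.0401). By fry 16 lists passed, among them these 13. In all, 3940 genes passed, 1703 higher and 2237 lower, and 1728 in the fit of the knockout arrays alone.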

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

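Tests chosen only after the result was seen were those of Mt2, of the Cre probe sets, of E2f1 and Gapdh in replicate 27, and of the retina against the markers of other cells. The tests of the slope of replicate 27 and of the carried-over retina were set before their results were seen.

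Single arrays stood apart in 55 of 820 tests of the 205 named genes in the 4 groups, where chance gives about 1 in 20 groups, or 41. Of these, 15 lay in knockout E17.5 replicate 28. Values are the distance to the nearest array divided by the range of the group. Knockout E17.5 replicate 28 had the highest value by 0.757 for Alas2, 0.733 for Airn, 0.764 for Slc25a37, 0.715 for Oas1a, 0.714 for Plvap, 0.831 for Asns, 0.790 for B2m and 0.830 for Rsad2, and the lowest value by 0.743 for E2f3, 0.75 for Egln1, 0.752 for Nsdhl, 0.841 for Dhcr7, 0.767 for Rb1, 0.901 for Trp53bp1 and 0.755 for Vim. Knockout P0 replicate 21 had the highest value by 0.886 for Pttg1 and 0.789 for Fdft1, and the lowest value by 0.761 for Mt1, 0.720 for Reln, 0.747 for Lrrn1, 0.763 for Trp53bp1, 0.818 for Bmp4 and 0.733 for Lhx2. Control E17.5 replicate 10 had the lowest value by 0.864 for Bmf, 0.803 for Xiap, 0.760 for Topbp1, 0.817 for Id3, 0.835 for Col5a1 and 0.723 for Ero1a. Control P0 replicate 1 had the highest value by 0.734 for Alb and 0.879 for Socs3, and the lowest value by 0.893 for Pnisr, 0.724 for Slc2a1 and 0.720 for Gstm1. Knockout P0 replicate 18 had the highest value by 0.712 for Aars, 0.987 for Alas2, 0.801 for Rpa2, 0.768 for Cks2 and 0.768 for Sulf2. Control E17.5 replicate 12 had the highest value by 0.797 for Pttg1, 0.729 for Ifi35, 0.897 for Id1 and 0.742 for Bpgm. Control P0 replicate 8 had the highest value by 0.762 for Tpm1 and 0.806 for Hsp90b1, and the lowest value by 0.842 for Ednrb. Knockout E17.5 replicate 27 had the highest value by 0.836 for Stat3, and the lowest value by 0.891 for Mt1. Control E17.5 replicate 15 had the lowest value by 0.714 for Paics and 0.726 for Pfkp. Knockout P0 replicate 22 had the highest value by 0.756 for Cdh1, and the lowest value by 0.757 for Cxcl1. Control P0 replicate 7 had the highest value by 0.730 for Pttg1. Control P0 replicate 5 had the highest value by 0.832 for Nbn. Control E17.5 replicate 11 had the highest value by 0.749 for Oas1a.

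Mt1 was high in the knockout arrays except E17.5 replicate 27, at 6.45 where the nearest knockout array of that stage lay at 10.43 and the lowest at P0, replicate 21, at 8.44. A control genotype of replicate 27 is where the tests part: the slope of its deviation on the P0 change, the test set beforehand, was -0.00407 and lay inside the range of the controls (-0.0922 to 0.142), which points toward a control array, while its E2f1 at 7.95 lay above the highest of all controls at 7.52 and its Gapdh 5' minus 3' signal at 0.157 above their highest at 0.0605, which a control array would not show. The slope alone does not settle genotype, since knockout replicate 24, with Mt1 at 10.91, also lay inside that range at 0.108, and a lens null for E2F1 and E2F2 in which Cre was absent or did not recombine E2f3 stays open and untested for replicate 27, which would make the knockout E17.5 group mixed (1541 genes with this array, 2502 without it). Induction of metallothionein genes by metal or stress cannot be told apart either, because the upper 95% limit of the change of Mt2, 0.820 at E17.5 with replicate 27 included, was 1.36 at P0, where Mt2 rose by 0.84 ± 0.25 (adjusted p = 0.0155), and Mt2 was 5.84 in knockout E17.5 replicate 24 but 7.38 in replicate 28, with Mt1 high in both and controls at most at 6.25. Mt1 sequence carried by the Cre transgene, absent or silent in replicate 27, cannot be told apart from these, because the Cre probe sets measure a spike-in control that was at least 12.8 in all 20 arrays, and a biological difference of this lens stays open and untested.

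Retina and pigment cell markers were higher in knockout lenses at P0, with retina markers such as Lhx2 at 8.63, Atoh7 at 7.99 and Otx2 at 7.86. Carried-over retina was tested as the whole cause of the rise of the replication list. The rise measured (54.1% ± 6.35 SE) exceeded the rise predicted from the control arrays (8.34% ± 10.3 SE) by 45.7 percentage points (SE 12.1). This test cannot decide, because the slope among controls was 0.0524 ± 0.0648 (SE) and the prediction was extrapolated. The retina level of the knockouts at 2.59 lay outside the control range of 0.586 to 1.31. Among knockout E17.5 arrays, replicates 25, 26 and 28 lay above 24 and 27 in the medians of both the retina and the replication list. Against a lower share of lens RNA that raises other cell types alike, retina minus endothelium markers differed by 1.71 (exact permutation p = 0.00794, the smallest possible), and retina minus erythroid, cornea, mesenchyme and muscle markers by 1.35 to 1.52 (adjusted p = 0.0111 over 7 lists), while retina minus macrophage markers, whose list was called too (median 0.83, 4 of 17 risen), was 0.64 (adjusted p = 0.130) and retina minus pigment cell markers 0.40 (adjusted p = 0.294). Of the 18 retina markers tested 0 belonged to another list, and 7 lay above the array median in all control P0 arrays (median change 0.58, 4 risen). Over these 7, no difference from markers of other cells that also lay above it passed after adjustment over 7 lists. By exact permutation it was 0.76 for endothelium (exact p = 0.0952) and 0.44 to 0.61 for erythroid, cornea, mesenchyme and muscle markers (adjusted p = 0.133 each). For macrophages it was -0.26 (adjusted p = 0.611) and for pigment cells 0.34 (0.287). A lower share of lens RNA is therefore not excluded. Carried-over retina as a part or the whole of the change, a lower share of lens RNA, and expression of these genes by knockout lens cells stay open, the last untested.

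The effect of the knockout differed between P0 and E17.5 by the test of the difference for 9 named genes, by -1.66 for Col4a3, -1.52 for Abi3bp, -1.17 for Tafa4, -1.02 for Pnisr, -0.96 for Rarb, 0.52 for Ak5, 0.77 for Aars, 1.04 for Ecrg4 and 1.13 for Ociad2. Each of these 9 genes lost its call in 13 (as Col4a3) to 19 (Pnisr) other settings of the processing. The count of 21 called genes fell to 0 without single arrays. The effect differed by the list test for 7 lists, with medians of 0.25 for replication, 0.49 for mitosis, -0.26 for lens epithelium, -0.15 for capsule and matrix, 0.72 for retina, 0.81 for pigment cells and 0.63 for macrophages, where no list passed with an estimated correlation (adjusted p = 0.841 for each of the 7 lists). By fry 0 of 31 lists passed.

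Probe sets without a single gene name stay out of the gene tests. Of 3161 such probe sets tested, 357 passed at E17.5 (167 higher, 190 lower) and 1073 at P0 (309 higher, 764 lower) in knockout against control.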

How the results depend on the processing

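Added after seeing the data were the fits without knockout E17.5 replicates 24 and 28, with Xist and with the retina markers as covariates. Of 249 results for named genes, 101 kept direction and call in each setting that tested them (66 of the 170 run in all 33 settings), 135 lost the call in at least 1, 13 gained it and 7 reversed. With every probe set on its own, which tests more features, 3735 (E17.5), 8090 (P0), 96 (difference of effects), 3540 (control stages) and 7830 (knockout stages) passed. Array weights gave 4293, 6482, 2585, 5088 and 6388 in that order. Fits of only the groups compared gave 343 at E17.5, 4431 for control stages and 1728 for knockout stages. The stricter filter gave 2325 genes and 5 lists for knockout stages, from fewer genes tested. With an estimated correlation 0 lists passed in each of the 5 comparisons. Without replicates 24 and 28, the difference had 221 genes, control stages 3117 and E17.5 10 lists. With the retina covariate, E17.5 had 1013 genes, P0 1498 and 7 lists, and the difference 1 gene and 3 lists (mitosis, lens epithelium and pigment cells), and 100 of the 249 results lost the call, 23 at E17.5, 68 at P0 and 9 of the difference. The cause was not tested for the other shifts.

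The mean of the probe sets reversed Dnaja1 (-0.00432), Ndrg1 (0.00735) and Sc5d (-0.0694) at E17.5 and Sc5d (-0.0459) and Bpgm (-0.0153) at P0. Without probe sets that match several transcripts, Ndrg1 at E17.5 was 0.0291, and at P0 Sulf2 was -0.34 and Cryl1 -0.50. The cause was not tested. Quantile normalization moved the higher and lower calls to 553 and 1423 at E17.5, 793 and 1163 for control stages, and 2220 and 1511 for knockout stages. Centring on medians gave 653 and 538, 398 and 1574, and 1168 and 2727.

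Leaving out 1 array gave 835 (control E17.5 replicate 10) to 2502 genes (knockout E17.5 replicate 27) at E17.5, 3058 to 4983 at P0, 0 to 321 for the difference, 1413 to 2987 for control stages and 3012 to 4956 for knockout stages. It gave 5 to 11 lists at E17.5 (11 without knockout replicate 28), 12 to 14 at P0, 5 to 10, 10 to 12 and 12 to 15 for the rest, and a correlation between stages of 0.625 to 0.769. No paired analysis was possible because the groups share no replicate number. No background level was measured, so falls that end below the array medians, such as Car8 at 3.98 ± 0.59 in knockout P0 arrays, are limited by signal over background.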

Other observations

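Tests chosen only after the result was seen were the exact permutation of list medians, the genes next to E2f1 and the Gapdh separation of genotypes. The splits of the arrays were set beforehand. The Xist and retina covariates were added after the data had been seen, the test with Xist before its own result was.

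Metabolic genes changed in part. Of 22 genes of hypoxia and glycolysis, 3 rose and 7 fell in knockout lenses at P0 (3 and 9 when adjusted over the list alone), with the lactate dehydrogenase gene Ldha at 0.64 ± 0.12 and the glucose transporter Slc2a1 at -0.66 ± 0.10 (SE). Of 15 cholesterol synthesis genes 1 rose and 5 fell at P0, with Dhcr7, which makes cholesterol in the last step, at -0.70 ± 0.12. Of 19 oxidative stress genes 8 rose and 3 fell, with Nqo1 at 0.52 ± 0.12 and catalase (Cat) at -0.54 ± 0.08. Camera did not call the 3 lists at P0 (adjusted p = 0.0536, 0.0536 and 0.154), while fry passed hypoxia (0.00873) and oxidative stress (0.00101) but not cholesterol synthesis (0.166). Under the retina covariate 1 hypoxia gene rose and 2 fell, 1 cholesterol gene fell, and 3 oxidative stress genes rose and 1 fell. Of 31 genes of Wnt, Notch and FGF signalling 9 rose and 5 fell, with Bmp4 at 2.01 ± 0.44 (1.43 and adjusted p = 0.0936 with the retina covariate) and Notch2 at -0.98 ± 0.18.

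Against control lenses at E17.5, the median of knockout lenses at P0 was 0.06 for replication, where control P0 lenses had -0.59, and -0.20 for mitosis, where control P0 lenses had -0.96. For G1 and S it was -0.07 against -0.55, for p53 targets 0.21 against -0.07 and for cholesterol synthesis -0.62 against -0.44. These medians were not tested.

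The median of each list was compared per array by exact permutation. At E17.5, 0 of 31 lists passed (smallest adjusted p = 0.164, 8 at an unadjusted p below 0.05), and at P0 13 of 31 passed, among them replication (0.63), mitosis (0.81), p53 targets (0.30), retina (1.53), hypoxia (-0.16) and oxidative stress (0.14) at the smallest adjusted p of 0.0246, and lens epithelium (-0.33), capsule and matrix (-0.32) and the unfolded protein response (0.14) at 0.0379. Heat shock (0.17, adjusted p = 0.0769) and macrophages (0.88, 0.0820), called by camera, did not pass.

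Changes in the same direction at both stages covered 941 genes. Against strain differences next to the E2f1 null allele as the whole cause, 2.66% of them (25 genes) lay among the 100 tested genes on either side of E2f1, where 12.5% of the 200 neighbours passed against 7.93% of all genes, and 12 of 769 other windows were as high, so a small part from this region is not excluded. Against unequal sex as the whole cause, 79.4% (747 genes) were still called at both stages with Xist as a covariate, and 369 were with the retina markers as a covariate, where the changes were 0.956 (E17.5) and 0.899 (P0) times those before and their SEs 1.06 and 1.33 times (medians over the 941 genes), so other tissue as a part of these changes stays open. RNA handling that differed between genotypes cannot be told apart from the knockout, because the lowest knockout array lay 0.0398 above the highest control in the Gapdh 5' minus 3' signal. The Cre transgene was present in the knockout groups only, so loss of E2F activity, as the design intends, and effects of Cre stay open.

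Splits of the same arrays were drawn 100 times, the real one included. For genes, chance can be excluded for E17.5 (1541, highest other 543, 1 split as large), P0 (4080, highest other 1187, 1 split) and control stages (2046, highest other 35, 1 split). For knockout stages (3940, highest other 3805, 1 split) chance is not called excluded. Another split came close to the real count there, and not all distinct splits were drawn. The 3805 genes of another split of the knockout arrays point to a structure of the samples, and the fit of these groups alone gave 1728 genes where 37.9% of the simulated calls of the fit with all groups were false. For the difference of effects (21 genes, 2 splits) the share of splits lay below the limit set beforehand, but chance is not called excluded. The highest other split called 2578 genes, which points to a structure of the samples other than the groups, and the count fell to 0 without single arrays. For the correlation between stages (0.728, 2 splits) the share of splits also lay below that limit. The highest other split reached a size of 0.740, so an arrangement other than the groups gave a correlation as large. For the number of lists chance cannot be excluded in any comparison, with 73 splits as large for E17.5 (6 lists, highest other 17), 7 for P0 (12, highest other 14), 52 for the difference (7, highest other 14), 21 for control stages (11, highest other 15) and 11 for knockout stages (13, highest other 17), and the E17.5 splits that called several times the real count point to a structure of the samples too.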
